A study of Homo sapiens with 10 samples.

How the data were processed

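The authors deposited one table of read counts, whole numbers of reads per guide RNA, with 43617 guides in 6 columns. Per the labels, the plasmid, day 0 and both day 8 columns each combine 2 sequencing runs, and each day 14 column is 1 run. Read 1 identified the guide and read 2 a barcode linked to it, per the labels' protocols. Whether barcodes entered the counts and which tool counted the reads are not given in the sources used here. The labels give a library of 43618 guides with 1000 non-targeting ones, a multiplicity of infection of 0.3 and 500 cells kept per guide. Day 0 was 6 days after transduction. The table also holds 7 deposited columns of log2 ratios between libraries. Recomputation showed that they are log2 ratios of raw count + 1 with no scaling for depth, so their medians carry depth. In the authors' deposited table the median log2 ratio of DMSO day 14 over day 0 was 0.33 over all guides. In the same authors' deposited column it was 0.51 over non-targeting guides, which also holds their rise relative to targeting guides. These columns were not used for the results, and 1 further column was empty.

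Guide identifiers pair a gene symbol with a chromosome and a position on hg38, the build in the submitters' processing notes. Which base of the target the position marks, and whether it counts from 0 or 1, is not given in the sources used here. Of 153 symbols, 151 matched the RefSeq gene table and 2, PRPF4B and CXorf56, matched as older symbols. Of the targeting guides, 99.7% lay inside the bounds of the named gene and 139 did not. Guide sequences, exons, codons and predicted edits were not analysed here, so the planned shares of stop and splice-site guides and the codon windows of SF3B1 and PHF5A are not reported. CDK11A, U2AF1, THOC3 and HSPA8 have near-identical copies in the genome, and their guides are uncertain in what they edit.

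Counts were scaled by the total of each library to CPM. The log2 ratio of CPM + 1 was centred on the median of the non-targeting guides. Guides under 5 CPM at day 0 (256 reads) were left out, which removed 1432 guides, 12 of them non-targeting, and left 41198 targeting and 987 non-targeting guides. The added 1 CPM shrinks changes of guides with few reads. A guide was called when it lay beyond the 1st or 99th percentile of the non-targeting guides at both day 8 and day 14. The share of non-targeting guides that passed is the measured background. Those limits were -0.78 and 0.63 for DMSO day 14 over day 0, and -1.35 and 1.15 for PB over DMSO at day 14. The non-targeting SD was 0.30 and 0.52 for the same ratios. Intervals on shares are Wilson or exact 95% binomial intervals, and fold intervals are exact and conditional on the summed reads. PCR reads are not independent molecules, so intervals cover counting error only.

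Gene medians and numbers of called guides were set against 10000 random lists of as many targeting guides, matched on 10 classes of day 0 abundance. All 153 genes had at least 10 guides. These percentiles describe the libraries and are not p-values, since guides of a gene are not replicates. A gene counted as having many called guides at 3 or more and at or above the 99th percentile. Of 23 gene lists, 20 had measured members. No SR protein, minor spliceosome or cap binding gene of the lists was measured, and 29 measured genes were in no list. The lists, the calling rule, the other settings tried and the rule for named genes were fixed before the data were examined. The 5 CPM filter in plasmid, the table of early loss and most tests of explanations came later. The rule took the 12 lowest and 6 highest gene medians in DMSO, the 12 genes with most gains and the 8 with most losses in PB, the 10 guides with the largest called change each way in PB and 5 each way in DMSO, 2 to 4 members per list, and SF3B1, PHF5A and SUGP1.

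The calling was tested on simulated data of 42129 guides past the filter, with changes that grew in proportion to days. For guides higher in PB it recovered 12 of 12 changed by 3.0 on the log2 scale, 6 of 12 changed by 2.0 and 1 of 13 changed by 1.0, and called 0.159% of unchanged guides. For guides depleted in DMSO it recovered 13 of 13 changed by -2.0 and 6 of 12 changed by -1.0, and called 0.169% of unchanged guides. For gene medians in DMSO it found 3 of 3 shifted genes and 1 of 150 unchanged ones. The noise of simulated guides was resampled from the same non-targeting guides that set the limits, whatever their abundance. The rates of calls on unchanged guides therefore restate the non-targeting background and are no independent check. Alternatives covered the pseudocount, the filter, the centring, the size factors, the days, the thresholds, the baseline and an edgeR quasi-likelihood fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.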

Results

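The series measured how often each guide RNA of a spliceosome-wide library was found in a culture of eHAP cells, a human haploid line, that expressed FNLS. FNLS is a cytosine base editor, a Cas9 nickase joined to a deaminase that makes C-to-T changes near the site a guide selects. The library covered 153 genes of the spliceosome and its partners with 42618 guides in the table, beside 999 non-targeting guides. The 6 libraries counted were the plasmid pool, the selected cells at day 0, and cells kept in DMSO or in 2 nM pladienolide B at days 8 and 14. Pladienolide B, called PB from here on, binds the SF3b part of the U2 snRNP and blocks branch site recognition. Each group was 1 library, so no difference has a replicate check. Total reads were 56235055 in plasmid, 51208751 at day 0, 47134555 in DMSO and 54228563 in PB at day 8, and 64738536 in DMSO and 54742712 in PB at day 14. The median guide had 1072 reads at day 0 and 1079 in PB at day 14.

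The first comparison asked which guides were lost while cells grew in DMSO. Guides against the Sm proteins SNRPD1 and SNRPE, which form the ring around spliceosomal snRNAs, had the lowest gene medians, at -0.43 over 44 guides and -0.42 over 33 guides (log2, day 14 over day 0). PHF5A, an SF3b subunit, followed at -0.41 over 49 guides. SMU1 at -0.37, PRPF38A at -0.36 and MFAP1 at -0.32, which all act in the B complex, were also low. So were LSM8 of the U6 LSm ring at -0.35, the helicase DDX39B at -0.33, the exon junction helicase EIF4A3 at -0.31 and the export adaptor ALYREF at -0.29. Each of these 10 genes lay below the 1st percentile of 10000 random lists of as many targeting guides matched on day 0 abundance. SF3B6 at -0.33 over 49 guides and LSM3 at -0.29 over 38 guides did not, at percentiles 3.23 and 7.99. In all, 18 genes lay below that percentile, where 1.53 of 153 would by chance. The other 8 were PRPF19, DHX15, PRPF8, CDK11A, THOC3, CTNNBL1, GPKOW and SF1.

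At the level of guides, 3250 of 41198 targeting guides (7.89%, Wilson 95% interval 7.63 to 8.15%) were depleted in DMSO on both days, against 1 of 987 non-targeting guides. The exact upper bound on the non-targeting rate corresponds to 232 targeting guides. The share of depleted guides was highest for LSM2, at 21.8% of 55 guides, and was 21.2% for SNRPE, 20.5% for SNRPD1, 20.4% for PHF5A, 17.9% for SMU1 and 16.4% for DDX39B. The lowest called guide was in SUGP1 at position 19316414 of chromosome 19, with 1297 reads at day 0 and 33 in DMSO at day 14, a change of -4.29. A CHERP guide (chromosome 19, 16529641) changed by -4.28, a CWC25 guide (chromosome 17, 38809698) by -3.98, an NKAP guide (chromosome X, 119925366) by -3.92 and an SF3A2 guide (chromosome 19, 2248159) by -3.79. The NKAP guide had 1 read left at day 14, and the counting interval of its fold decrease ran from 147 to 32456.

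Among gene lists with more than 1 measured gene, the depleted share was highest in the LSm ring at 10.5% of 579 guides. Of its 61 depleted guides LSM4 held 25, LSM7 13, LSM2 12 and LSM8 5, and LSM2 alone exceeded the limit of random lists of its size. It was 9.97% in the B complex proteins, 9.91% in the Sm ring, 9.31% in the U5 snRNP, where PRPF8 had 145 depleted guides, SNRNP200 78 of 1071 (7.28%, below the list share) and EFTUD2 54, and 9.13% in the U2-associated factors, where SF1 had 85, PUF60 48 of 421 (11.4%) and CHERP 56 of 699 (8.01%, below the list share). The counts in the LSm ring (limit 59), the U5 snRNP (380) and the U2-associated factors (460) lay above the 99th percentile of matched random lists. The Sm ring with 53 guides and the B complex with 129 did not reach theirs, at 59 and 133. List medians gave another order. The B complex at -0.22, the U5 snRNP at -0.21, the U2-associated factors at -0.20 and the ATPases at -0.19 lay below the 1st percentile of random lists, as did DHX15 alone at -0.27, while the LSm ring at -0.19 lay at percentile 18.0 and the Sm ring at -0.21 at percentile 5.30. Medians of the cyclophilins at -0.12, the U2 snRNP core at -0.09 and the Prp19-related proteins at -0.16 lay above the 99th. Shares were 8.72% in SF3b, 7.67% in SF3a, 9.12% in the Prp19 complex, 7.87% in the U4/U6 and tri-snRNP proteins, 8.12% in the exon junction proteins and 8.53% in the ATPases. They were 7.07% in the Bact and RES proteins, 7.02% in the catalytic-step factors, 6.65% in the G-patch proteins, 6.60% in the Prp19-related proteins, 6.51% in the U1 snRNP, 6.37% in the cyclophilins and 6.12% in the U2 snRNP core. DHX15, the only measured member of the disassembly list, had 36 depleted guides of 256 (14.1%) against a limit of 32, and RBM25, the only one of the hnRNP list, had 16 of 295.

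Genes with the highest medians in DMSO were DDX5 at -0.00024, SNRPB2 at -0.0059, PPIL3 at -0.016, FRA10AC1 at -0.02, FAM50B at -0.03 and LUC7L3 at -0.07. All 6 lay above the 99th percentile of random lists. These medians hold change after day 0 only, so losses before day 0 are not in them. At the main settings no gene of the 153 had a median above 0 relative to the non-targeting guides. DDX5 and SNRPB2 turned to just above 0 under some of the alternatives given below. Enrichment of single guides in DMSO did not stand out from background. The 130 enriched targeting guides (0.316%) compare with 3 of 987 non-targeting guides (0.304%), a rate that predicts 125. A PRCC guide on chromosome 1 at 156797289 changed most, from 1269 reads at day 0 to 15116 in DMSO at day 14, a change of 3.01 where the highest non-targeting guide reached 1.00, a value that 22 of the 130 exceeded. In PB the same guide had 1133 reads at day 14. The next 4 were in MTREX at 1.90, DDX23 at 1.68, SNRPF at 1.59 and FAM50B at 1.24.

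The second comparison asked which guides gained or lost in PB relative to DMSO. PHF5A guides led the gains. The guide at position 41467600 of chromosome 22 had 463 reads in DMSO and 47223 in PB at day 14, 121-fold by CPM (counting interval 110 to 132), and the guide at 41467610 had 84 and 11145. All 5 called PHF5A guides lay between 41467456 and 41467610, a stretch of 155 bp that held 21 of the gene's 49 measured guides, and their changes were 6.79, 6.54, 4.76, 3.79 and 3.67. The 16 other guides in that stretch had a median of 0.44. Together the 5 guides made up 0.154% of PB reads and 0.0036% of DMSO reads at day 14. The other guides among the 10 largest called gains were in SUGP1 (chromosome 19, 19277046) at 4.45, PRPF31 (chromosome 19, 54118315) at 3.98, U2AF2 (chromosome 19, 55661762) at 3.48, PRPF4B (chromosome 6, 4042526) at 3.42 and SF1 (chromosome 11, 64767074) at 3.31. The highest non-targeting guide reached 1.59. Against day 0 the PRPF4B guide changed by 0.53 in PB, inside the non-targeting 99th percentile of 1.08, and by -2.89 in DMSO. Its gain over DMSO is thus mainly a loss in DMSO. Each of the other guides among the 10 lay above 1.08 in PB against day 0, from 1.44 for PRPF31 to 5.56 for PHF5A at 41467600.

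**Figure D1:**
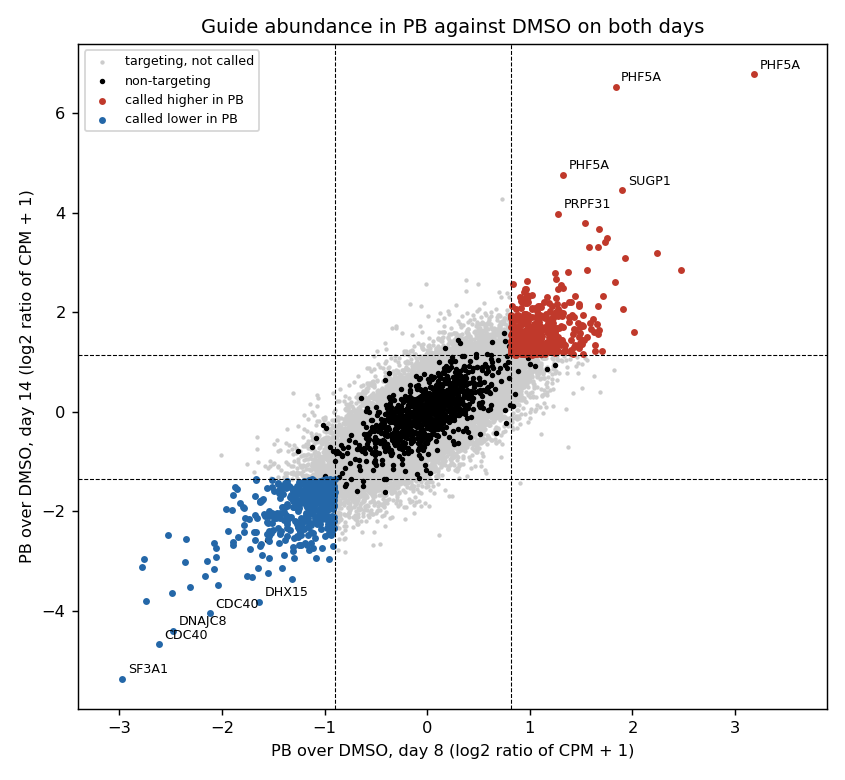
Log2 ratio of CPM + 1 in PB over DMSO at day 8 (horizontal) and day 14 (vertical), one point per guide, with dashed lines at the 1st and 99th percentile of the 987 non-targeting guides (black). The 460 guides called higher in PB (red) and 425 called lower (blue) lie beyond the lines on both days, and PHF5A guides reach 6.79 at day 14.

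Losses in PB were led by an SF3A1 guide on chromosome 22 at 30346359, with 3385 reads in DMSO and 13 in PB at day 14, a change of -5.37. CDC40, a second-step splicing factor, had 4 of the 10 largest called losses. They lay on chromosome 6 at 110217699 (-4.67), 110180483 (-4.05), 110217700 (-3.53) and 110201599 (-3.48). The guide at 110217700 had 713 reads in DMSO and none in PB at day 14. The rest were in DNAJC8 (chromosome 1, 28214978) at -4.40, DHX15 (chromosome 4, 24529682) and HSPA8 (chromosome 11, 123058813), each at -3.82, SF3A3 (chromosome 1, 37978802) at -3.64 and the PRCC guide named above at -3.37. Of the 10, the PRCC guide was the only one that was also called enriched in DMSO.

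In total 460 targeting guides (1.12%, Wilson 95% interval 1.02 to 1.22%) were higher in PB on both days and 425 (1.03%, 0.938 to 1.13%) were lower. Among non-targeting guides 1 and 2 of 987 passed, and the exact upper bounds on those rates correspond to 232 and 301 targeting guides. Of the 460, 134 also rose above day 0 in PB beyond the non-targeting 99th percentile, while 235 had fallen below the 1st percentile in DMSO at day 14, and 24 did both. Of the 425, 369 fell below the 1st percentile in PB against day 0. The numbers of calls rest on the threshold: day 14 alone gave 1287 and 1049. With limits set within 3 classes of abundance, 234 of the 460 and 343 of the 425 were called again.

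Gene by gene, most calls for gain were in SRRM2 with 20, SNRNP200 with 17, PRPF4B and SF1 with 14 each, THOC2 with 13, PRPF8 with 12, DDX39B and RBM10 with 9 each, BUD13 and RBM42 with 8 each, and PLRG1 and HSPA8 with 7 each. SRRM2, SNRNP200, PRPF8, RBM10, BUD13, RBM42 and HSPA8 stayed below the 99th percentile of random lists of their size. SRRM2, for example, had 1360 guides and a limit of 24. The 8 genes at or above their limit were PRPF4B, SF1, THOC2, DDX39B, PLRG1, PHF5A, SNU13 and TXNL4A. PRPF4B, a kinase of the tri-snRNP, had 5.26% of 266 guides called and a median of 0.28. Medians above the 99th percentile also included PHF5A at 0.34, DDX39B at 0.27, the branch point protein SF1 at 0.24, RBM10 at 0.19, SRRM2 at 0.16, THOC2 at 0.12 and EIF4A3 at 0.14, among 20 such genes. The EIF4A3 median was of the other sign at day 8, at -0.03. DDX39B, EIF4A3 and PHF5A were also among the lowest genes in DMSO, and SF1 and GPKOW (0.14 in PB over DMSO) lay below the 1st percentile there. Against day 0 the PB medians were -0.16 for DDX39B, -0.30 for EIF4A3 and -0.14 for GPKOW, where that of all targeting guides was -0.20. The high medians of these 3 genes over DMSO therefore do not show a rise in PB. For PHF5A and SF1 the gene medians against day 0 are not given here, so theirs are not read as a gene-wide rise either.

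Among calls for loss SF3B3 had 20, SF3A3 19, CDC40 18, PUF60 and SF3A1 17 each, and HSPA8, U2AF2 and CACTIN 11 each, all above the 99th percentile of random lists, as were DHX35 with 10 and SNRPA1 with 5. DDX41, DHX15, SF3B4 and WDR83 were at their limits of 9, 7, 8 and 6, which makes 14 genes at or above the limit. CDC40 had the lowest gene median at -0.57 (quartiles -1.10 and -0.03 over 207 guides), with 76.3% of its guides below 0. SF3A3 was at -0.32, SF3B3 at -0.28, CACTIN at -0.27, SF3A1 at -0.23 and U2AF2 at -0.16, all below the 1st percentile, as were 24 genes in all. PUF60 at -0.06 and HSPA8 at -0.06 were not, at percentiles 2.94 and 11.5.

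**Figure D2:**
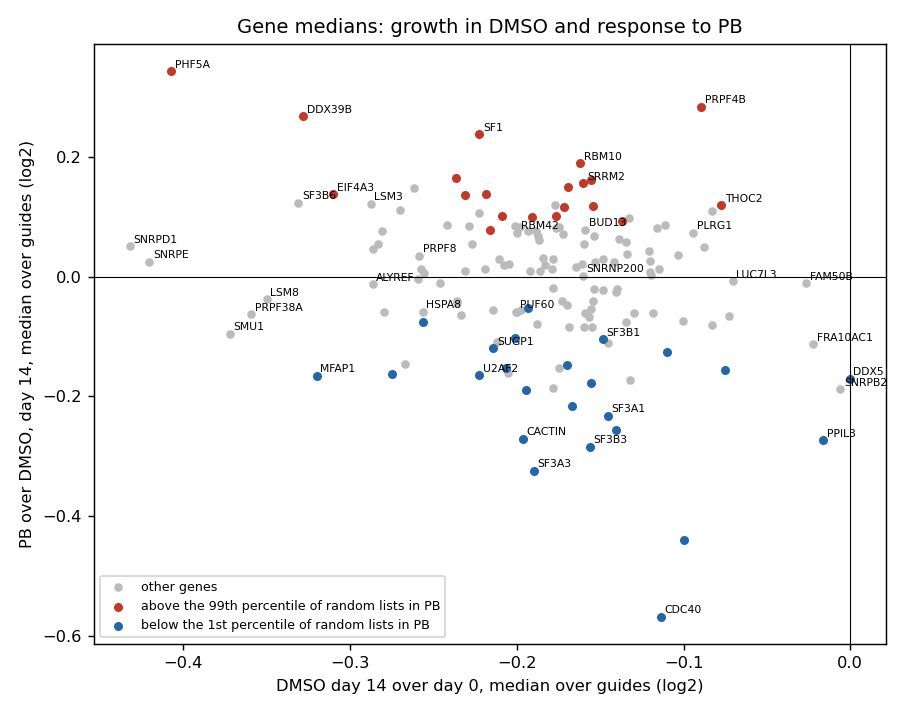
Median log2 ratio over the guides of each of the 153 genes, DMSO day 14 over day 0 (horizontal) against PB over DMSO at day 14 (vertical), with genes beyond the random-list percentiles in PB in red (20 above) and blue (24 below). CDC40 lies lowest in PB at -0.57 and PHF5A highest at 0.34. The axes share the DMSO day 14 library, so a correlation between them is not read.

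By list, 39 of 1161 SF3a guides (3.36%, 2.47 to 4.56%) and 37 of 1939 SF3b guides (1.91%, 1.39 to 2.62%) were lower in PB, above the limits of 20 and 33 from matched random lists. Of the SF3a calls, SF3A3 held 19, SF3A1 17 and SF3A2 3. In SF3b, SF3B3 alone held 20, SF3B4 8, SF3B2 6 and SF3B1 3, and PHF5A, SF3B5 and SF3B6 had none, so the list passes its limit through SF3B3. The list medians in PB were -0.17 for SF3a, -0.17 for SF3b and -0.19 for the U2 snRNP core, each below the 1st percentile. The catalytic-step factors had 81 guides lower in PB against a limit of 71, with CDC40 at 18, CACTIN at 11 and DHX35 at 10, and a median of -0.08. DHX15, alone in the disassembly list, had a median of -0.16, below the 1st percentile. At the other end, the Bact and RES proteins had 22 guides lower in PB where random lists averaged 44.8, with a median of 0.10, and the U5 snRNP had 27 where they averaged 44.1, with a median of 0.04. Its members differed, with PRPF6 at 0.14, SNRNP200 at 0.0020 and EFTUD2 at -0.06. The U1 snRNP median was 0.09 and that of the exon junction proteins 0.08, both above the 99th percentile, as were the tri-snRNP proteins at 0.05, the G-patch proteins at 0.04 and the U2-associated factors at 0.03. The losses of the U2-associated factors ran the other way, with 69 guides lower in PB where random lists averaged 53.9 (limit 70), among them 17 of PUF60 and 11 of U2AF2. No list had more guides higher in PB than the 99th percentile of its random lists. The Sm ring, LSm ring, B complex, Prp19 complex, Prp19-related, hnRNP and ATPase lists had PB medians between the 1st and 99th percentile. The cyclophilin median was -0.06, below the 1st percentile, with PPIL3 at -0.27 and PPIG at -0.16. The intervals treat guides of a list as independent, which overlapping guides are not.

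**Figure D3:**
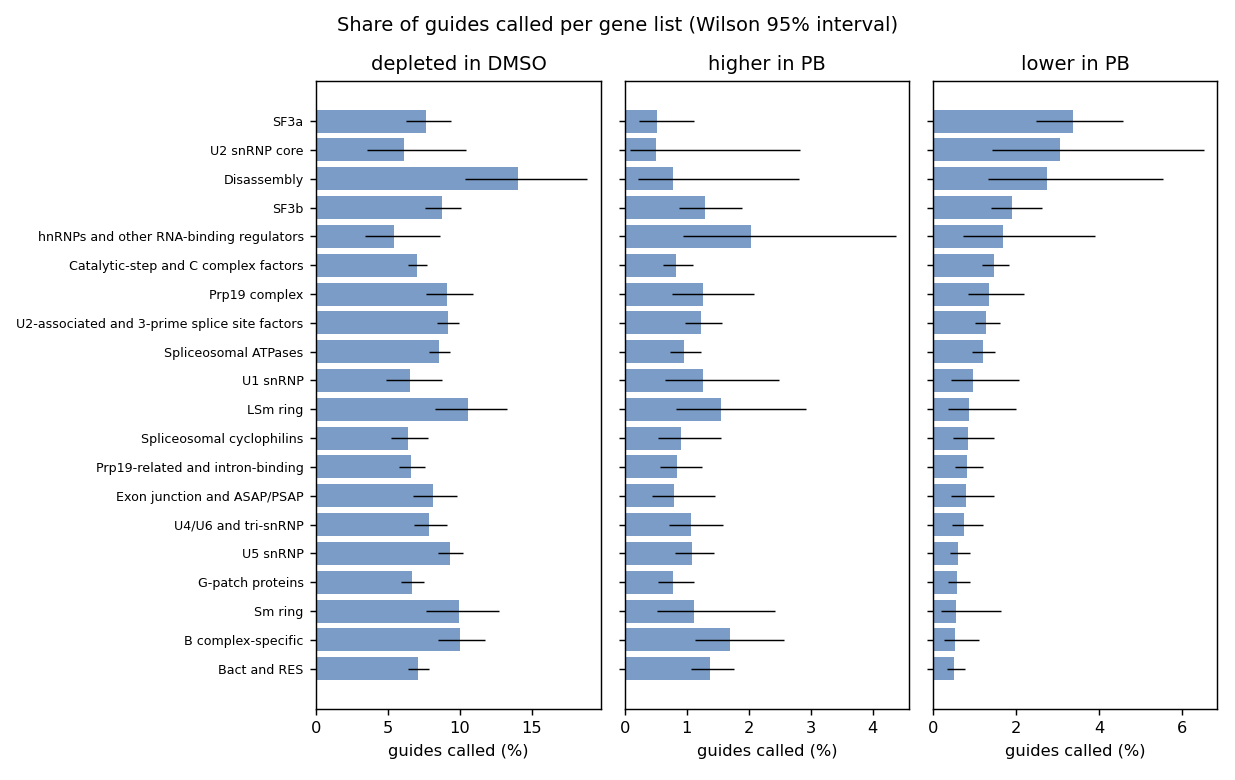
Percent of the guides of each gene list called depleted in DMSO, higher in PB and lower in PB, with Wilson 95% intervals. SF3a has the highest share lower in PB at 3.36% and the Bact and RES list the lowest at 0.505%.

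SF3B1, which carries most of the PB binding site together with PHF5A, had 5 called gains and 3 called losses among 411 guides and a median of -0.10. The largest called gains were 2.46 at position 197402086 and 2.30 at 197393133 of chromosome 2, and the largest loss was -2.17 at 197396186. One SF3B1 guide at 197397992, chosen here after its values were seen, had 1928 reads in DMSO and 31471 in PB at day 14. Its change of 4.29, 19.3-fold by CPM, was the 5th highest of all guides that day. It was not called because its day 8 ratio of 0.73 lay under the limit of 0.81. In all, 151 uncalled guides lay above the highest non-targeting guide at day 14 and 4 below the lowest. SUGP1, a G-patch protein that works with SF3B1, had 4 gains and 4 losses among 469 guides. Of its gains, 3 lay between 19277046 and 19277852 of chromosome 19, at 4.45, 1.58 and 2.79, and the other was 1.28 at 19316504. Its losses lay between 19297341 and 19305877, from -2.17 to -1.65. In neither direction did SF3B1 or SUGP1 reach the limit of random lists of its size. Over all targeting guides 1.12% were called higher and 1.03% lower, so these numbers of calls do not set the 2 genes apart.

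**Figure D4:**
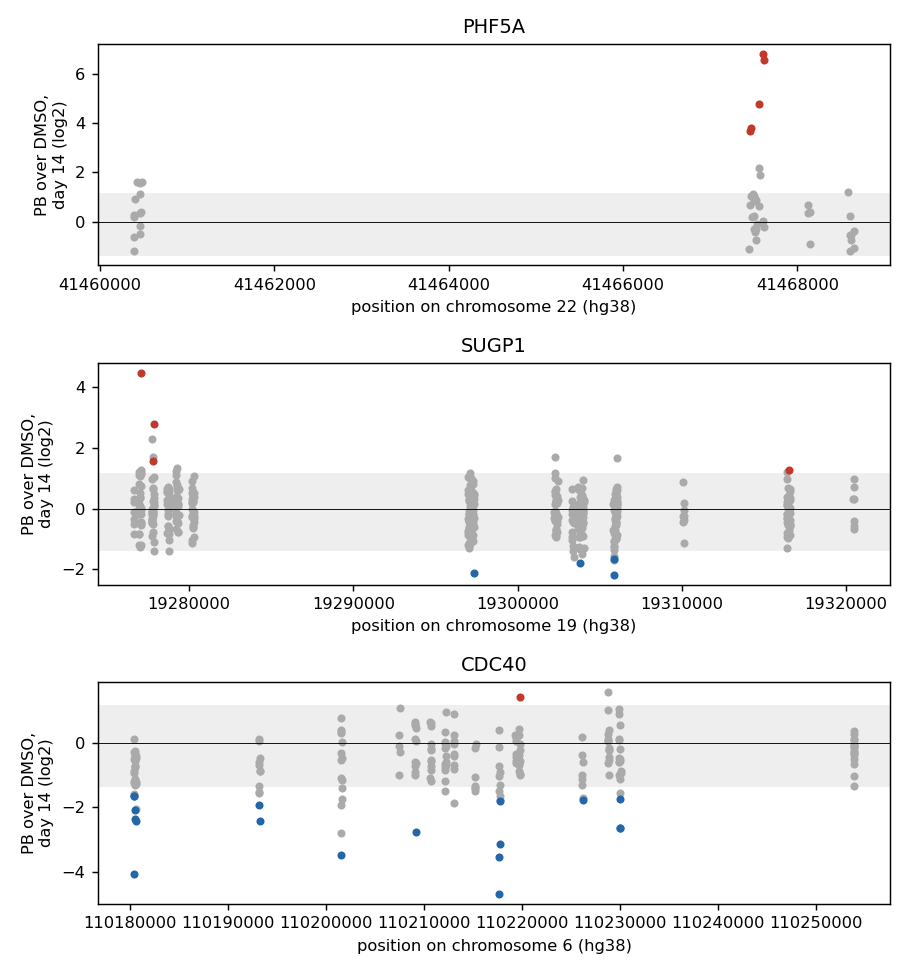
Log2 ratio in PB over DMSO at day 14 by genomic position for the guides of PHF5A, SUGP1 and CDC40, with called gains in red, called losses in blue and the range between the non-targeting 1st and 99th percentile shaded. The 5 PHF5A gains sit within 155 bp, while the 18 CDC40 losses span 49628 bp.

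Called guides of a gene tended to lie near each other. Among guides lower in PB, 13.4% had another such guide of the same gene within 10 bp, where 1000 shuffles within genes gave at most 11.5%. The share was 10.4% for guides higher in PB, where shuffles reached 7.83%, and 45.3% for guides depleted in DMSO, where they reached 28.2%. It was 0 for the 130 guides enriched in DMSO, inside the range of 0 to 6.15% over their shuffles. Across guides, which are not independent replicates, the PB over DMSO ratios of days 8 and 14 correlated with r = 0.76 for targeting and r = 0.71 for non-targeting guides. Both days sample the same cultures, so that agreement includes shared drift.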

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

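The tests below were chosen after the results they bear on were seen, except the test of neighbouring guides among those that fell in DMSO.

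One guide, SF3B3 at 70563960 of chromosome 16, lay beyond the non-targeting limits in opposite directions on the 2 days, at 0.90 on day 8 and -1.43 on day 14, on 245 and 11 reads in PB. The difference was not tested.

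Among 499 targeting guides that were above 5 CPM in plasmid but left out at day 0, 23 were higher in PB on both days. ISY1 at 129137139 of chromosome 3 had 1017 reads in plasmid, 20 at day 0, none in DMSO and 103 in PB at day 14. In the other direction, 19 of the 499 and 1 of the 5 non-targeting guides left out were lower. With 5 such non-targeting guides no background can be set, and the limits came from more abundant guides, whose spread is smaller.

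Of the 460 guides higher in PB, 235 had fallen in DMSO, so the gain may be a smaller loss. If PB merely cost cell divisions, guides already falling before the arms were split would lose less in PB. The 3275 guides below the non-targeting 1st percentile at day 0 over plasmid had a median PB over DMSO ratio of 0.0070 (bootstrap 95% interval -0.028 to 0.039). The interval holds 0, so by its rule the test does not decide. Against day 0 the same guides had day 14 medians of -0.76 in DMSO and -0.83 in PB. As a set they thus showed no clearly smaller loss in PB, and 0.039 is far below the 1.15 limit for a called gain. The answer moves with the selection: 360 guides below -1 had a median of -0.11 (-0.20 to -0.0020). If single guides drifted independently in DMSO, neighbours would not gain together. Of the 235, 10.2% had another within 10 bp, where 1000 shuffles had a mean of 5.12% and a range of 0 to 11.5%. The share lay in the upper tail of the shuffles but not beyond them. That leans against independent drift without deciding it, so drift stays open, as does an effect of the drug.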

How the results depend on the processing

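Some results depended on the limits and others did not. Every one of the 400 values of the 29 named guides under an alternative kept its direction and its call. Those guides were chosen as the largest called changes in the same data, so their stability says little about the other calls. Values are ordered as enriched in DMSO, higher in PB and lower in PB. Day 14 alone gave 347, 1287 and 1049 guides against 130, 460 and 425. Limits at 2.5% of non-targeting guides per tail gave 271, 895 and 827, and at 0.5% gave 48, 165 and 273. For guides enriched in DMSO, the 10 CPM filter gave 79, limits within abundance classes 84 (59 of them shared) and even-numbered non-targeting guides 72. In PB, limits within abundance classes called 416 higher and 505 lower, of which 234 and 343 were among the 460 and 425. The edgeR fit with day as a block called 5079 higher and 5060 lower in PB, but also 105 and 110 of 987 non-targeting guides; with serial samples and 1 residual degree of freedom it does not measure differences between cultures. Depleted guides in DMSO (2587 to 4719) and the 8 genes with many gains (7 to 10) stayed within 1.5 times the main count. So did the 18 genes with a low DMSO median (15 to 23), except that random lists of non-targeting guides gave 147 genes, as most targeting guides lie below them. Of the 18, 12 were shared with the plasmid baseline and 12 with day 8.

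Centring on all targeting guides shifts DMSO medians up by 0.18 and cannot change calls. It turned the DMSO medians of DDX5 to 0.18, SNRPB2 0.17, PPIL3 0.16, FRA10AC1 0.16, FAM50B 0.15, LUC7L3 0.11, THOC2 0.10, PRPF4B 0.089 and PLRG1 0.085. DDX5 also turned to 0.0011 with a pseudocount of 0.1 CPM and 0.0021 without the filter, and SNRPB2 to 0.0027 with 0.1 CPM and 0.0066 with 10 CPM. At day 8 the EIF4A3 median in PB was -0.032. The cause was not tested. Among other gene medians 67 moved beyond their interval and 489 did not, and among list shares 146 moved and 274 did not.

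The 5 CPM filter in plasmid was chosen after seeing the data and gave 478 higher and 347 lower in PB. The shares of stop and splice-site guides under any setting, editing windows included, were not run. No paired analysis was possible because the numbers 1 and 2 in the labels are sequencing runs that share one column, which leaves no replicates to pair; the fit with day as a block pairs the arms within each day only. Changes of under 2.0 on the log2 scale in PB were often missed in simulated data. Simulated changes grew in proportion to days, so recovery of changes that come mostly after day 8 was not tested.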

Other observations

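The tests of CDC40 and of non-targeting spread were chosen after the results were seen.

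Losses were visible before treatment. At day 0 over plasmid, with the filter set on plasmid, 6.53% of 41587 targeting guides (Wilson 95% interval 6.30 to 6.77%) lay below the non-targeting 1st percentile. PRPF38A had the highest share at 27.5% of 142 guides (20.8 to 35.3%), then LSM2 at 25.4%, SNRPE at 23.5%, TXNL4A at 22.2% and BCAS2 at 22.1%. MFAP1 had 21.8% of 165 guides. These genes were chosen after their values were seen.

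Among the 29 genes outside the lists, the kinases SRPK1 and SRPK2, which phosphorylate SR proteins, had DMSO medians of -0.10 and -0.08, above the 99th percentile. The kinase CDK11A had -0.26 and THOC3 of the THO complex -0.26, both below the 1st, while THOC2 of the same complex had -0.08, above the 99th. At day 8 the CDK11A median in DMSO lay at percentile 17.6. CDK11A and THOC3 have near-identical copies in the genome, so what their guides edit is uncertain. In PB, PRCC had a median of -0.15, below the 1st percentile.

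CDC40 guides lay low in PB over most of the gene, with the 18 called losses spanning a stretch that held 186 of 207 guides. Chance assignment of guides to genes is argued against, since the lowest median of any gene of 100 or more guides over 10000 relabelings was -0.28, against -0.57. A rise in the DMSO arm alone is argued against, since in PB against day 0, which uses no DMSO library, the CDC40 median was -0.66 (bootstrap 95% interval -0.78 to -0.48) and the lowest of 10000 random lists of 207 guides was -0.39. In DMSO the CDC40 median of -0.11 lay at percentile 97.9 of random lists, so a small part from that arm stays open. A sensitivity of CDC40-edited cells to PB may explain the shift as a hypothesis, but whether guides with no predicted edit shared it was not analysed here.

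Non-targeting guides with fewer reads spread more between arms. Over 5 classes of day 0 abundance the SD of PB over DMSO at day 14 fell from 0.65 to 0.36, with a slope of log2 SD on log2 reads of -0.51 (bootstrap 95% interval -0.62 to -0.41). A slope of -0.5 is what sampling of few cells per guide would give, so such sampling is a candidate source. Counting of reads would give that slope too, and the slope does not separate them. Counting error alone, at the median non-targeting guide, would give an SD of 0.052, where the observed SD was 0.52. That argues against read counting as the main source of this spread. No biological explanation was tested.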
